A study of Homo sapiens with 12 samples.

How the data were processed

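The series profiled RKO, an established human colorectal carcinoma cell line, by ribosome profiling (Ribo-seq, which sequences the mRNA fragments protected by ribosomes) and by RNA-seq. Its 12 samples form 6 groups of 2 by their labels: Ribo-seq of control cells, of RPL22L1 knockdown cells, of RPL22L1 overexpressing cells and of an RPL22L1 immunoprecipitation (IP), and RNA-seq of control and of knockdown cells. The libraries numbered 2 were used, 1 per group, and the other 6 samples were not analysed here. Per the labels' protocols, RNA was taken up in TRIzol, a part of each extract went to RNA-seq and the larger part to Ribo-seq, and libraries were made with a small RNA kit. How the knockdown, the overexpression and the immunoprecipitation were done is not given in the sources used here. The labels give the overexpressing genotype to the earlier IP library, so the Ribo-seq library labelled overexpression was taken as the input of the IP.

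The authors deposited 1 table per library with an RPKM value (reads per kilobase and per 1000000 reads) for each gene, 1 transcript per gene, together with the start and end of its coding sequence and its transcript length. The submitters' processing notes name the GRCh38 build, bcl2fastq 2.0 and DESeq2. The aligner, the annotation and the counting program are not given in the sources used here. The unit was checked on the values. Multiplied by the coding length in kilobases (Ribo-seq) or the transcript length in kilobases (RNA-seq), the deposited RPKM values of each library summed to 1000000, and all of them were whole multiples of 1 read within a tolerance of 0.001. So Ribo-seq values count reads per coding length and RNA-seq values count reads per transcript length, each per 1000000 counted reads. The reads recovered in this way were 1819345 for the control Ribo-seq library, 2209757 for the knockdown, 5206543 for the library labelled overexpression, 6083144 for the IP, 22307280 for control RNA and 20616149 for knockdown RNA. They were used to state depth and counting intervals and not for a count test.

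The tables do not share 1 annotation. Control and knockdown Ribo-seq list the same 12510 genes on the same transcripts, and of the transcripts found in GENCODE 29 (GRCh38), 96.7% had the same length there. The library labelled overexpression and the IP list 12953 and 13110 genes on another transcript set, with the same length in GENCODE 29 for 40.9% and 41.3%. Control and overexpression tables share 11617 genes by Ensembl gene ID, of which 10667 had the same transcript and coding length. Comparisons across these tables therefore also compare separately made tables. Gene coordinates, gene types and genomic spans were taken from GENCODE 29, and coding GC content from its transcript sequences where the length matched.

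Changes were computed as the difference of log2(RPKM + 1) between 2 libraries, centred on the median change of all genes with a mean of at least 5 RPKM over the libraries compared. The pseudocount of 1 understates the change of low genes. The change of translational efficiency (TE) was the Ribo-seq change minus the RNA-seq change, for genes with a mean of at least 5 RPKM in each assay. There were 5 comparisons: knockdown against control in Ribo-seq, in RNA-seq and in TE, overexpression against control in Ribo-seq, and IP against its input in Ribo-seq. With 1 library per group no test was run and no p-value is given. A gene was counted as higher or lower when it changed 2-fold or more, a description of size that compares libraries and not conditions. Counting intervals are exact 95% intervals (Clopper-Pearson) of the ratio of reads of 2 libraries, without the pseudocount and with the same centring. For low genes the log2 change can therefore lie outside them. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. The floor of a library was 3 reads, and a fold against a library with 0 reads was computed against it with the same centring.

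All genes named, gene lists, filters and thresholds were fixed before the data were examined, unless stated otherwise. Named genes were RPL22L1 and its paralog RPL22 and, in each comparison, the 10 protein-coding genes with the largest rise and the 10 with the largest fall among genes with a mean of at least 10 RPKM (for TE, in each assay), and up to 4 members with the largest absolute change of each list described. A few genes that meet this rule are not reported here. The 27 gene lists covered homologous recombination, Fanconi anaemia, non-homologous end joining, mismatch repair, nucleotide excision repair, base excision and single-strand break repair, the DNA damage checkpoint, p53 targets, cytosolic large-subunit and small-subunit ribosomal proteins, other TOP mRNAs (mRNAs with a 5' terminal oligopyrimidine tract), ribosome biogenesis, mitochondrially encoded mRNAs, nuclear-encoded oxidative phosphorylation, mitochondrial ribosomal proteins, abundant non-coding RNAs, replication-dependent histones, DNA replication, G2/M and mitosis, ATF4 and the unfolded protein response, interferon-stimulated genes, 5-fluorouracil and nucleotide metabolism, drug efflux transporters, apoptosis regulators, cholesterol synthesis, epithelial and mesenchymal markers, and markers of other cell types. Symbols were matched to Ensembl gene IDs through current names. Each list with at least 5 members past the filter has its median change placed among 10000 random lists of the same size, matched on 10 bins of mean expression. The random lists were not matched on coding GC or genomic span. A list was said to stand apart under percentile 2.5 or over 97.5. The list of abundant non-coding RNAs had 0 members past the filter and gave no value.

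The steps were tested on simulated libraries drawn from the real proportions and depths. Among 59 genes simulated at 2-fold in the Ribo-seq comparison of knockdown and control (8536 genes), 100% had the right direction and 35.6% were counted, and of 67 genes at 4-fold 100% were counted. In the RNA-seq comparison (8162 genes), 14.0% of 57 genes at 2-fold and 100% of 64 genes at 4-fold were counted. In TE (7616 genes), 34.4% of 61 and 100% of 58 were counted. In overexpression against control (8267 genes), 44.3% of 70 and 98.5% of 65 were counted. In IP against input (8481 genes), 41.4% of 70 and 100% of 55 were counted. Of 200 simulated lists of 30 unchanged genes, between 2.5% and 7.0% stood apart in the 5 comparisons, and with a 1.5-fold shift 100% did. The simulated genes varied independently by counting error alone, without trends with GC or span. These rates therefore need not hold for real lists, whose genes can vary together. Libraries drawn 20 times from unchanged proportions gave a mean of 57.9 counted genes in Ribo-seq of the knockdown, 0 in RNA-seq, 29.3 in TE, 37.5 in overexpression against control and 3.45 in IP against input.

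Alternatives fixed beforehand were pseudocounts of 0.1 and 5, filters at a mean of 1 and 20 RPKM and none, no centring, rescaling to equal totals without centring, and control cells as the reference of the IP. A minimum of 50 reads, a restriction to genes with the same transcript in both tables, and a restriction of the Ribo-seq comparisons to genes with a mean of at least 1 RPKM in RNA-seq were added after the data were seen. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.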

Results

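Ribosome footprints and RNA were measured in RKO cells, a colorectal carcinoma line, with altered levels of RPL22L1, a paralog of the large-subunit ribosomal protein RPL22. Footprints were available from control cells, from RPL22L1 knockdown cells, from cells labelled as overexpressing RPL22L1 and from an RPL22L1 immunoprecipitation, and RNA from control and knockdown cells. Each group is represented by 1 library, so the values have no replicate check. The libraries held 1819345 counted reads (control footprints), 2209757 (knockdown footprints), 5206543 (labelled overexpression), 6083144 (IP), 22307280 (control RNA) and 20616149 (knockdown RNA). The series title points to translation by ribosomes that carry RPL22L1, DNA repair and drug resistance, and the gene lists described here were fixed for that question.

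RPL22L1 (ENSG00000163584, chromosome 3, 170864875 to 170870483, minus strand, GRCh38) was lower in both knockdown libraries. Its footprints stood at 3374 RPKM in control cells (2247 reads) and at 1123 RPKM in the knockdown (908 reads), a log2 change of -1.81 with a counting interval from -1.92 to -1.70. Its RNA stood at 95.4 RPKM in the control and 42.7 RPKM in the knockdown, a log2 change of -1.21 (interval -1.31 to -1.15). In the library labelled overexpression RPL22L1 was not raised: its footprints stood at 3221 RPKM, a log2 change of -0.09 against control (interval -0.16 to -0.02), and in the IP at 2807 RPKM. A transgene without the counted coding sequence would not be seen in these values. RPL22 (ENSG00000116251, chromosome 1, 6185020 to 6209389, minus strand) had footprints of 1072 RPKM in the control, 801 RPKM in the knockdown, 1387 RPKM in the library labelled overexpression and 1173 RPKM in the IP, and RNA of 110 RPKM and 114 RPKM in control and knockdown. The log2 changes of RPL22 were -0.64 in knockdown footprints, -0.02 in RNA, 0.35 in the library labelled overexpression and -0.33 in the IP. RPL22 and RPL22L1 are similar in sequence and RPL22 has pseudogenes, so reads shared between copies leave both values uncertain.

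**Figure D1:**
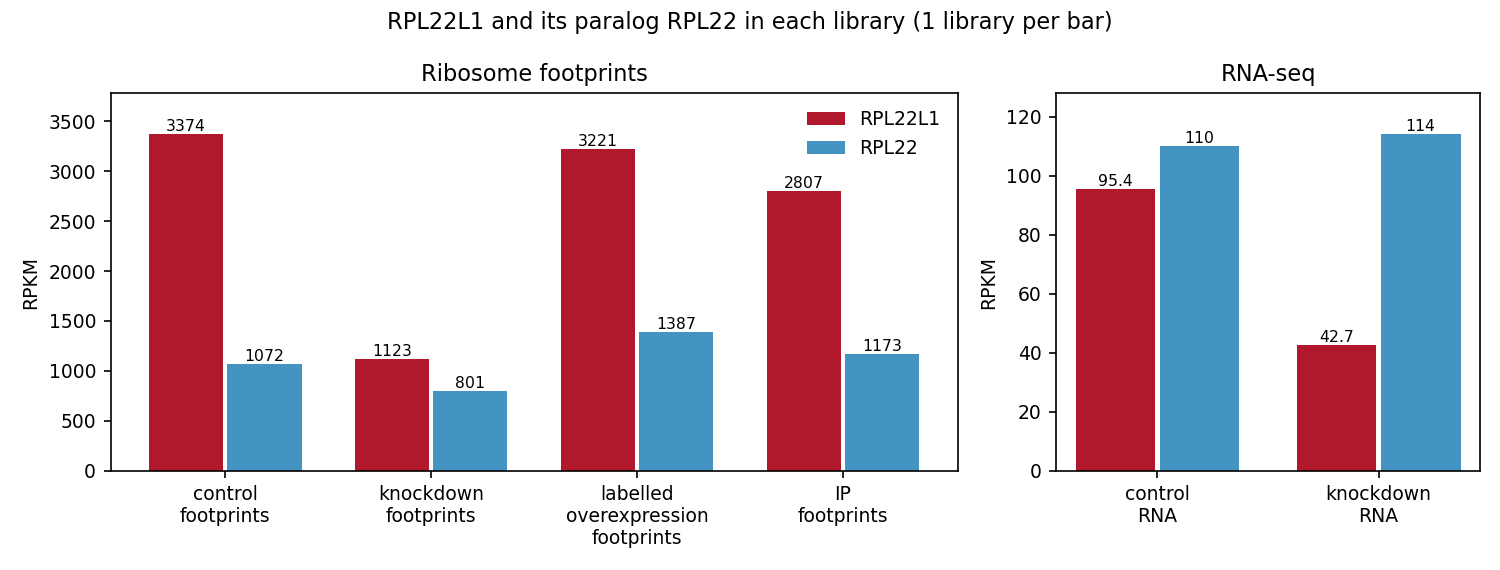
RPKM of RPL22L1 and RPL22 in the 4 footprint libraries and the 2 RNA libraries, 1 library per bar. RPL22L1 footprints were 3374 RPKM in the control, 1123 RPKM in the knockdown and 3221 RPKM in the library labelled overexpression.

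In footprints, knockdown against control showed a broad rise of p53 target genes and a fall of histone and ribosomal protein genes. Of 28 p53 targets past the filter, 25 rose 2-fold or more and 0 fell, with a median log2 change of 1.88, above all 10000 random lists. Replication-dependent histone genes, which package newly made DNA, had a median of -1.93, with 20 of 21 lower by 2-fold or more. Genes of the large ribosomal subunit had a median of -0.67 (45 genes), those of the small subunit -0.66 (33 genes) and other TOP mRNAs -0.67 (18 genes, percentile 0.01 in a second draw of random lists), the ribosomal protein lists below all random lists, although only 5, 2 and 3 of their members passed 2-fold, and rescaled to equal totals without centring the 3 medians were -0.43, -0.42 and -0.43.

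The largest footprint rises were led by genes of the p53 response. FDXR, the mitochondrial ferredoxin reductase, rose by 3.09 on the log2 scale (47 reads in the control, 599 in the knockdown), BTG2, an inhibitor of proliferation, by 2.95, GDF15, a secreted stress cytokine, by 2.94, and BBC3, the apoptosis activator PUMA, by 2.58. ATF3, a stress-induced transcription factor, rose by 3.20. TP53INP1, a p53 cofactor in stress responses, changed by 4.57, but on 1 read in the control against 76, with an interval from 3.22 to 11.07. ACER2, an alkaline ceramidase, rose by 2.81, CRIP2, a LIM-domain protein, by 2.67 (3 reads in the control, interval 1.54 to 5.54), and NATD1, a protein with an acetyltransferase domain, by 2.55 (2 reads in the control, interval 0.86 to 6.03). MTRNR2L13, a humanin-like gene whose sequence resembles mitochondrial ribosomal RNA, had 4 reads against 0, too few for a fold.

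The largest footprint falls came from histone genes and from genes of long span. HIST1H1D, a linker histone, fell with a log2 change of -3.10 (1227 reads in the control, 202 in the knockdown), and HIST2H2BF, a core histone, with -2.52. MAD1L1, a spindle checkpoint protein, changed by -3.70, VTI1A, a SNARE of the Golgi, by -3.03, LPP, a focal adhesion protein, by -2.97, and FAF1, a cofactor of the VCP segregase, by -2.77. BRE (now BABAM2), a subunit of the BRCA1-A complex, changed by -2.65 (63 reads in the control, 12 in the knockdown), and SMYD3, a lysine methyltransferase, by -2.63. These genes span 417 kb (MAD1L1), 372 kb (VTI1A), 737 kb (LPP), 523 kb (FAF1), 449 kb (BRE) and 758 kb (SMYD3). MT1A, a metallothionein, changed by -2.56, and MTRNR2L8, another humanin-like gene, by -2.66. Histone genes are nearly identical to each other and metallothionein genes are close copies, so single members are uncertain.

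DNA repair lists stayed within the range of random lists in footprints. The medians were 0.01 for homologous recombination (34 genes), 0.12 for Fanconi anaemia, -0.23 for non-homologous end joining (percentile 5.30), -0.03 for mismatch repair, -0.12 for nucleotide excision repair, -0.05 for base excision and single-strand break repair and 0.01 for the DNA damage checkpoint. Individual members moved: XRCC4, the partner of DNA ligase IV in end joining, changed by -2.33, LIG3, a ligase of single-strand breaks, by -1.33, DDB2, a p53 target that recognises ultraviolet damage, by 2.09, and PCNA, the sliding clamp, by 1.06. Drug efflux transporters had a median of 0.11, with ABCC4 at -1.94, ABCC1 at -1.15 and ABCB6 at 1.38. The list of 5-fluorouracil and nucleotide metabolism had a median of 0.00, with RRM2B, the p53-induced ribonucleotide reductase subunit, at 1.62 and UPP1, uridine phosphorylase, at -1.47. Of 316 genes spanning over 200 kb, 143 fell 2-fold or more in footprints (45.3%), and random lists were not matched on span. Falls of single list members, here and below, were not separated from that trend.

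Of the remaining lists, ribosome biogenesis was lower in footprints (median -0.43, below all random lists, led by DDX10 at -1.35 and UTP20 at -1.15; -0.20 without centring and -0.19 rescaled to equal totals), as was G2/M and mitosis (-0.28, percentile 0.355, with PLK1 at -1.03), though its median was only -0.06 without centring and -0.04 rescaled to equal totals. Interferon-stimulated genes were higher (0.49, percentile 99.8, with IFI6 at 1.24; 0.72 rescaled), and so were mitochondrially encoded mRNAs (0.24, percentile 99.3, 7 members with values; 0.47 without centring and 0.48 rescaled). Within the random range were apoptosis regulators (0.09, with PMAIP1 at 1.91 and BIK at 1.84), ATF4 and the unfolded protein response (-0.15, with DDIT4 at 2.31), DNA replication (-0.12, with POLA1 at -1.28), cholesterol synthesis (-0.19), nuclear-encoded oxidative phosphorylation (-0.02), mitochondrial ribosomal proteins (-0.15), epithelial and mesenchymal markers (-0.08) and markers of other cell types (-0.05, 6 members). In all, 404 of 8547 genes were higher and 358 lower by 2-fold or more. The median gene stood 0.22 higher on the log2 scale before centring, and without centring 725 were higher and 236 lower (75.4% higher). Lists of mismatch repair, nucleotide excision repair, and ATF4 and the unfolded protein response had means of 0.12, 0.05 and 0.19, opposite in sign to their medians, and drug efflux transporters a mean of -0.21.

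Some footprints came from genes with almost no RNA in these cells or no RNA value here. SPARC, a matrix protein, had 72 footprint reads in the control and 103 in the knockdown but 0 and 1 reads in RNA, and the collagen gene COL1A1 had 111 and 159 footprint reads against 6 and 14 in the far deeper RNA libraries. Without an RNA value, CSH1, a placental lactogen, had 34 footprint reads in the control and 217 in the knockdown, a log2 change of 2.12, and PAPPA, a placental protease, had 34 and 246, a change of 2.08. These 4 genes were chosen after their values were seen.

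RNA-seq of the same cells showed the same rise of p53 targets, no fall of ribosomal protein mRNAs and a fall of mRNAs from long genes. Of 28 p53 targets, 23 rose 2-fold or more, with a median log2 change of 1.93, above all random lists. CDKN1A, the cell cycle inhibitor p21, rose by 2.06 (3309 reads in the control, 13545 in the knockdown), GDF15 by 3.46, BTG2 by 3.04, FDXR by 2.43 and BBC3 by 2.24. SESN1, a stress-responsive inhibitor of mTORC1 signalling, rose by 2.48, TP53I3, a quinone oxidoreductase, by 2.30, FAS, the death receptor, by 2.22, PLK3, a stress-responsive kinase, by 2.15, and ATF3 by 3.13. The medians of large-subunit and small-subunit ribosomal protein mRNAs were both -0.04, and that of other TOP mRNAs was -0.16, within the random range.

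Among the largest RNA falls were RPTOR, the scaffold of mTORC1, at -3.09 (2660 reads in the control, 186 in the knockdown), GALNT18, of the family that starts mucin-type glycosylation, at -2.63, PARD3, a cell polarity scaffold, at -2.47, CMSS1, a nucleolar protein of small-subunit assembly, at -2.39, SND1, a Tudor-domain nuclease, at -2.24, SEPT9, a septin, at -2.11, MAP1LC3C, an autophagy protein, at -1.97, and COG5, a Golgi tethering subunit, at -1.93. Apart from MAP1LC3C (3.58 kb), these genes span from 220 kb (SEPT9) to 706 kb (PARD3); RPTOR lies on chromosome 17 from 80544819 to 80966371. Of the 185 genes lower by 2-fold or more, 148 span over 100 kb, which is 80.0% against 13.9% of all 8178 genes. The median RNA change was -0.77 for 273 genes over 200 kb (interval -0.88 to -0.66), -0.24 for 864 genes of 100 to 200 kb, and between 0.00 and 0.08 in the shorter classes. Footprints followed, with a median of -0.87 over 200 kb, while TE did not (-0.04). The grouping by span was chosen after the values were seen.

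**Figure D2:**
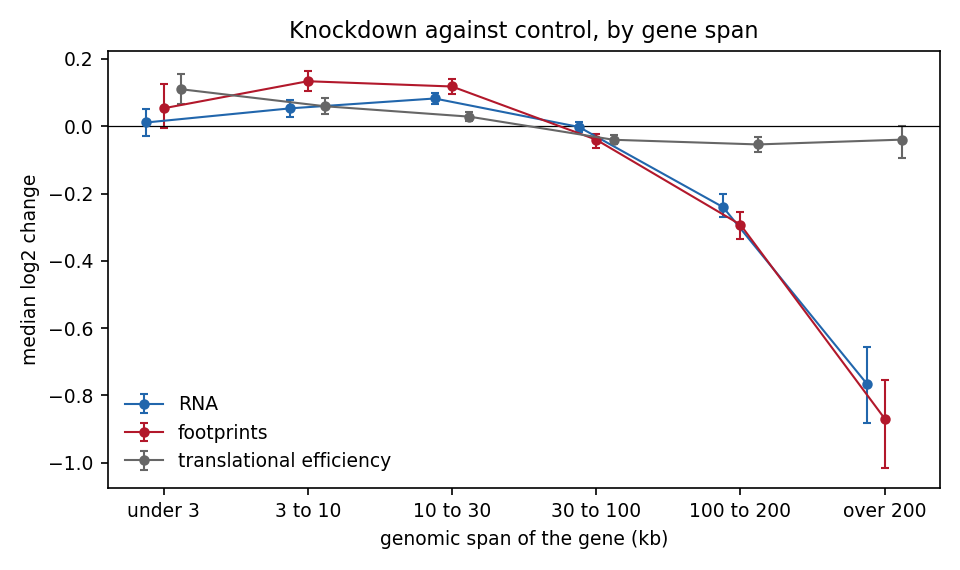
Median log2 change of knockdown against control by genomic span of the gene in kb, for RNA, footprints and translational efficiency, with 95% intervals of the median across genes. RNA and footprints fell together in the classes of 100 to 200 kb and over 200 kb, while translational efficiency stayed near 0.

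Other RNA lists that stood apart were mitochondrially encoded mRNAs (0.70, with MT-CO1, a subunit of cytochrome oxidase, at 1.06), interferon-stimulated genes (0.49, with MX1 at 0.70), apoptosis regulators (0.25, percentile 99.6), ribosome biogenesis (-0.28, with DDX10 at -1.55), non-homologous end joining (-0.23, percentile 1.66, with PRKDC, the DNA-dependent kinase, at -0.71) and cholesterol synthesis (-0.22, percentile 1.18, with LSS at -0.86). Of these, non-homologous end joining and cholesterol synthesis stood apart under 6 of 8 alternatives and apoptosis regulators under 7. Homologous recombination had a median of 0.17 (percentile 95.9) and Fanconi anaemia of 0.19, inside the random range. Histone mRNAs were scarcely seen in RNA, with a median of 2.01 RPKM in knockdown RNA against 366 RPKM in knockdown footprints, and the 6 members past the filter had a median change of 1.02 (HIST1H2BD at 1.47), or 0.52 over 22 members with no filter. In total 130 genes were higher and 185 lower, and counting error alone gave 0.

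**Figure D3:**
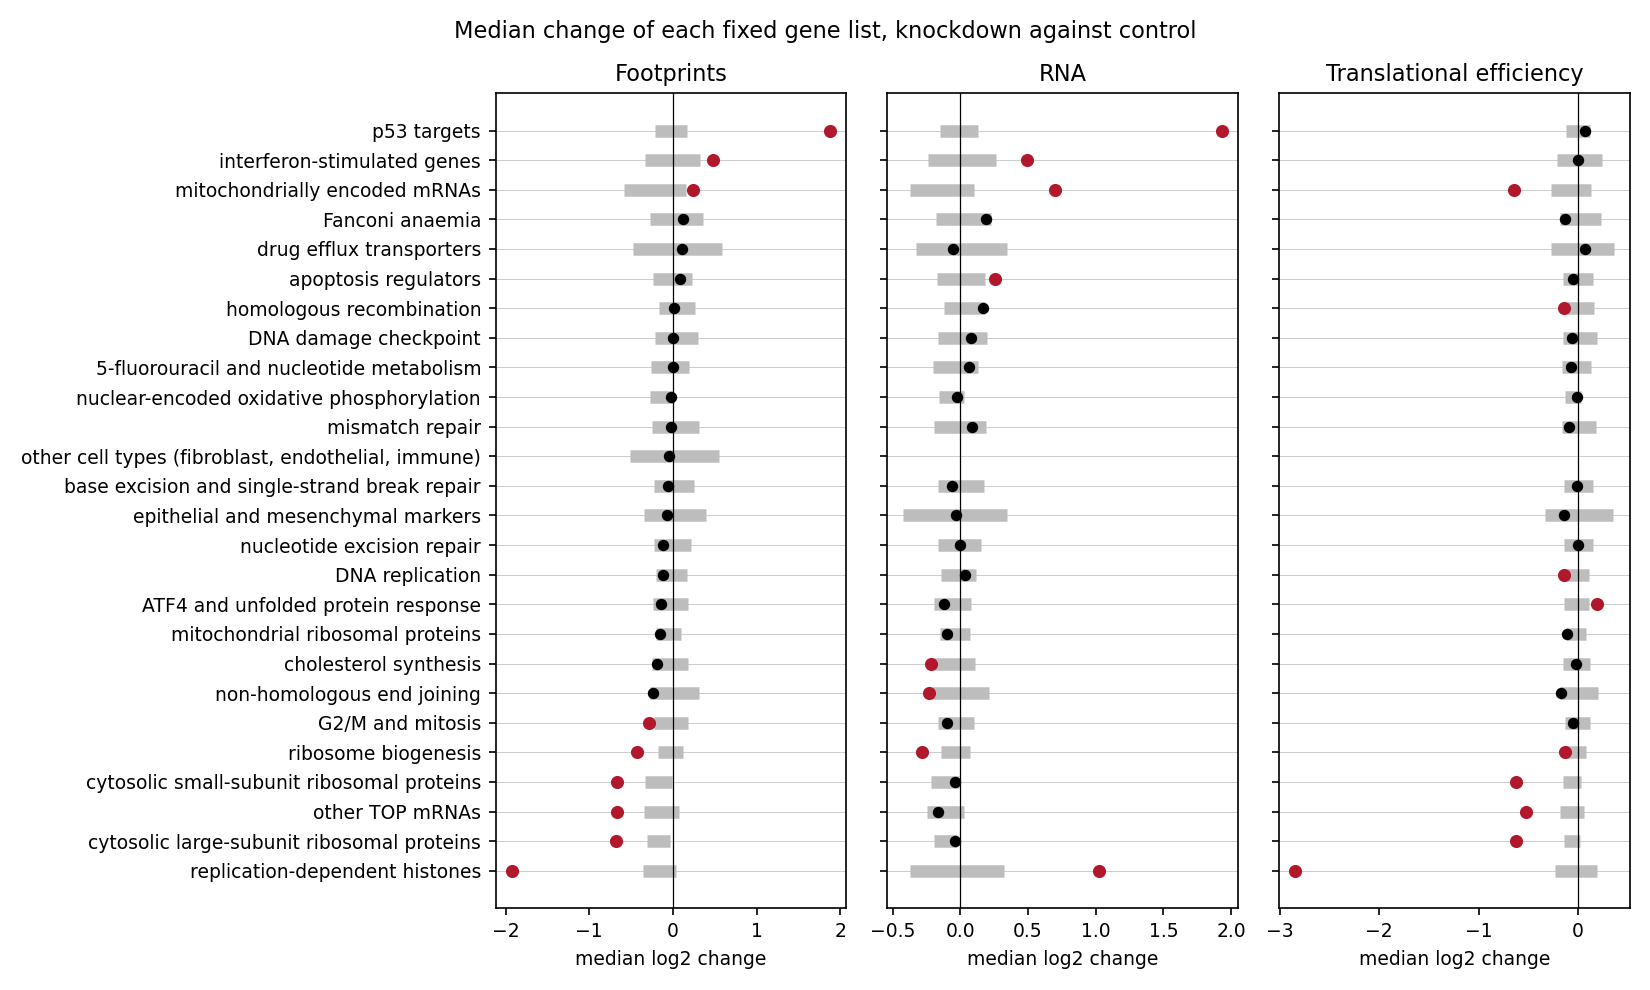
Median log2 change of each gene list in footprints, RNA and translational efficiency, knockdown against control; grey bars hold the central 95% of random lists and red points lie outside them. Targets of p53 stood at 1.88 in footprints, 1.93 in RNA and 0.07 in translational efficiency.

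Translational efficiency, footprints relative to RNA, fell for ribosomal protein mRNAs as a class. The median log2 change was -0.62 for 44 large-subunit mRNAs and -0.63 for 33 small-subunit mRNAs, and -0.53 for 18 other TOP mRNAs, each below all random lists, and rescaled to equal totals without centring they were -0.38, -0.39 and -0.29. RPL12 (-1.47), RPLP1 (-1.40) and RPLP0 (-1.30), which form or adjoin the stalk of the large subunit, RPS12 (-1.27) and RPSA (-1.17) of the small subunit were among the 10 largest falls. RPS29 stood at -1.40 but did not meet the mean of 10 RPKM in each assay required for that ranking. Among other TOP mRNAs, the initiation factor EIF4B was at -1.02 and the elongation factor EEF1A1 at -0.94. RPL22L1 itself was at -0.60 and RPL22 at -0.63, close to the medians of these lists.

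The list of p53 targets had a TE median of 0.07 (percentile 87.2), so its rise in footprints matched that in RNA. Histone mRNAs had the lowest values, HIST1H2BK at -2.86, HIST1H1C at -2.56 and HIST1H2BH at -1.47, with RNA higher while footprints were lower. HIST1H2BK stood at 58.0 RPKM and 135 RPKM in control and knockdown RNA and HIST1H1C at 31.8 RPKM and 63.5 RPKM. Histone mRNAs were scarcely seen in RNA, with a median of 2.01 RPKM in knockdown RNA against 366 RPKM in knockdown footprints. Their footprint to RNA ratios therefore need not measure translational efficiency, and no change of histone translation is concluded from them. Mitochondrially encoded mRNAs had a median of -0.65 (percentile 0.0300), or -0.41 rescaled. The list of ATF4 and the unfolded protein response was higher (0.19, or 0.43 rescaled, percentile 99.9, with DDIT3, a stress transcription factor, at 1.08). Homologous recombination (-0.14, percentile 1.11), DNA replication (-0.14, percentile 1.02) and ribosome biogenesis (-0.13, percentile 1.52) stood slightly low relative to the median gene. Without centring, which adds the same amount to every gene, their medians were 0.02, 0.02 and 0.03 and their places among random lists did not change. All 3 lay inside the random range with a filter at 20 RPKM (-0.04, -0.12 and -0.11), and homologous recombination also with a pseudocount of 5 (-0.10). TE changes rose with coding GC (rank correlation 0.35 across genes), on which random lists were not matched. The other repair lists lay within the random range (non-homologous end joining -0.17, Fanconi anaemia -0.13, mismatch repair -0.09, DNA damage checkpoint -0.06, base excision -0.01, nucleotide excision 0.01), with means of opposite sign for mismatch repair (0.01), base excision (0.03) and nucleotide excision (-0.01). RMI1, of the complex that dissolves recombination intermediates, was at -0.91, and POLL, a polymerase of end joining, at 0.96 (13 footprint reads in the control).

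The largest TE rises rested on few control footprints. RHBDD3, a rhomboid-like protein, changed by 1.81 with 8 control reads, TMEM160, a mitochondrial membrane protein, by 1.81 with 18, FAM58A (cyclin Q) by 1.81 with 9, CARKD (NAXD, an enzyme that repairs damaged NADH) by 1.46 with 10, C8orf82, a little-studied mitochondrial protein, by 1.43 with 8, CTDNEP1, a nuclear envelope phosphatase, by 1.36 with 18, SEPW1, a selenoprotein, by 1.34 with 10, CHIC2, a palmitoylated vesicle protein, by 1.27 with 11, NINJ1, which mediates membrane rupture in cell death, by 1.25 with 13, and PEMT, which makes phosphatidylcholine, by 1.23 with 20. The remaining falls were ZCRB1, a protein of the minor spliceosome, at -1.30, and PAPD4, a cytoplasmic poly(A) polymerase, at -1.17. Over 7639 genes, 78 were higher and 28 lower; counting error alone gave 29.3. The median shift before centring was 0.16, and without centring 152 were higher and 21 lower (87.9% higher, against 73.6% with centring).

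The library labelled overexpression was compared with control footprints to see what more RPL22L1 does, but RPL22L1 was not raised in it, and the values compare separately made tables. Changes in this comparison fell with coding GC (rank correlation -0.43 across genes), on which random lists were not matched. Histone footprints were lower (median -1.52, 16 of 21 by 2-fold or more, with HIST2H2AC at -2.72). The control library, which the knockdown comparison shares, had the highest histone median of the 4 footprint libraries (1233 RPKM, against 366 RPKM in the knockdown, 482 RPKM in the library labelled overexpression and 839 RPKM in the IP). Genes of cholesterol synthesis were lower (-0.99, 10 of 21, with EBP at -2.25, SREBF2, the sterol-responsive transcription factor, at -1.62, and DHCR7 at -1.49). Targets of p53 were higher (0.57, 8 of 28, with GADD45A at 1.53 and MDM2 at 1.21; 0.91 over 20 members with a filter at 20 RPKM). Mitochondrially encoded mRNAs had a median of 1.10 and a mean of 0.56, with 4 of 7 higher by 2-fold or more (MT-ND6 at 1.46) and MT-ND4L (-0.89) and MT-ATP6 (-0.32) below the median gene. Ribosomal protein lists did not stand apart (large subunit -0.04 with a mean of 0.02, small subunit -0.01), nor did other TOP mRNAs (-0.08).

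Of 8322 genes, 531 were higher and 432 lower in the library labelled overexpression. Many extreme changes sat in genes that the tables count on other transcripts: ALDOA, a glycolytic aldolase (-9.11), ABCF2, an ATP-binding cassette protein without membrane domains (-7.21), HBE1, an embryonic globin (-6.68, 2 reads, interval -10.84 to -5.90), and FKBP2, a prolyl isomerase of the endoplasmic reticulum (-5.41). Counted on the same transcript were falls such as those of HIST1H2AD, a core histone (-7.27), MTRNR2L8 (-6.57, 1 read, interval -12.36 to -4.48), ARPC1B, a subunit of the actin nucleator Arp2/3 (-4.67), SOD2, the mitochondrial superoxide dismutase (-4.33), and FAM103A1, the activator of the mRNA cap methyltransferase (-4.13). The 10 largest rises were all on the same transcript: RAP1B, a small GTPase (5.37), FXR1, an RNA-binding protein (4.06), STC1, a secreted stanniocalcin (3.97, 53 against 2471 reads), ID1, an inhibitor of differentiation factors (3.90), ATP5E, a subunit of ATP synthase (3.81), MTG1, a mitochondrial ribosome GTPase (3.79, 2 control reads, interval 2.79 to 7.73), PPP3R1, the regulatory subunit of calcineurin (3.44), SMIM10L1, a small membrane protein (3.35, 2 control reads, interval 1.66 to 6.64), NF2, the merlin tumour suppressor (3.25), and ABHD16A, a lipase of phosphatidylserine, which had 182 reads against 0, at least 20.9-fold higher against the floor (counting interval from 4.07 on the log2 scale). An equal transcript name does not exclude another treatment of paralogs and pseudogenes, which FXR1 and ATP5E have.

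Of the DNA repair lists, mismatch repair stood apart in this library by the narrowest margin, with a median of 0.37, and did so under 3 of 10 alternatives and not in a second draw of random lists (percentile 97.4). The others lay within the random range: homologous recombination 0.11 with RAD50 at -1.78, non-homologous end joining 0.17, Fanconi anaemia 0.11, nucleotide excision repair 0.14, base excision repair -0.08 (mean 0.01) and the checkpoint list 0.16. Drug efflux transporters were at -0.64 (percentile 1.97, 6 members, 6 of 10 alternatives outside the random range). Epithelial and mesenchymal markers had a median of 0.55 with a filter at 5 RPKM, which was 1.00 for genes on the same transcript and turned to -0.39 with a filter at 20 RPKM and to -0.06 with none. In that list KRT19 was at 2.81 and KRT8 at 2.17, keratins of simple epithelia, while FN1, the matrix protein fibronectin, had 0 reads against 186 in the control, at least 180-fold lower against the floor (counting interval up to -7.18). COL1A1 had 0 reads against 111, at least 107-fold lower (counting interval up to -6.43). FN1 has no RNA value here and COL1A1 almost no RNA in control cells, so whether their control footprints came from these cells is not known.

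The immunoprecipitate was compared with its input, the library labelled overexpression, to see which mRNAs sat on ribosomes recovered with RPL22L1. RPL22L1 footprints were at -0.28 (interval -0.33 to -0.23). Mitochondrially encoded mRNAs, which mitochondrial ribosomes translate, were depleted: all 7 with values fell 2-fold or more, with a median of -2.27, and MT-CO1 (-3.29, 69775 reads in the input and 8840 in the IP), MT-ND6 (-2.79), MT-ND5 (-2.53), MT-ATP8 (-2.27) and MT-ATP6 (-2.03) were 5 of the 10 largest falls. Ribosomal protein mRNAs were modestly lower, with medians of -0.33 for the large and -0.39 for the small subunit and -0.35 for other TOP mRNAs (EEF1B2 at -1.13), the ribosomal protein lists below all random lists and the other TOP mRNAs at percentile 0.02 in a second draw of them; rescaled without centring the medians were -0.23, -0.28 and -0.24.

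The genes highest in the IP included some of epithelial junctions, keratins, secreted ligands and histones, while the junction genes OCLN (-0.05) and TJP1 (0.26) and the keratin KRT18 (0.45) did not pass 2-fold. CST6, a secreted cystatin, had 73 reads against 0, at least 19.6-fold higher against the floor of 3 reads (counting interval from 3.96 on the log2 scale). TNFAIP3, the NF-kB inhibitor A20, changed by 3.95, DKK1, a Wnt antagonist, by 3.94, CRIP1, a LIM-domain protein, by 3.92, MALL, a protein of membrane rafts, by 3.82, GTSF1, a cofactor of piRNA-guided silencing, by 3.69, CLDN7, a tight-junction claudin, by 3.63, AREG, an EGF receptor ligand, by 3.25, and CXCL3, a chemokine, by 3.20 (2 reads in the input, interval 2.07 to 7.11). Epithelial and mesenchymal markers had a median of 0.45 (percentile 99.8, 5 of 11 higher), which was 0.11 (percentile 78.0, inside the random range) for members with at least 1 RPKM in RNA-seq, 1.21 with a filter at 1 RPKM and 0.81 with none, with CLDN4 (3.29, 2 input reads, interval 2.68 to 7.68), KRT19 (3.15) and KRT8 (3.12). These markers were low in control cells: KRT8 stood at 5.38 RPKM in control footprints, 28.1 RPKM in the input and 267 RPKM in the IP. Histones had a median of 0.73 (8 of 23 higher, led by HIST1H3J, a core histone, at 4.45), which turned to -0.77 against control cells as the reference.

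Among the other lists, interferon-stimulated genes (0.50, with OASL at 1.63), apoptosis regulators (0.27, with BIRC3 at 2.60), p53 targets (0.18, percentile 98.4, with BBC3 at 1.55) and cholesterol synthesis (0.29, with MVD at 1.07; -0.74 against control cells) were higher, and homologous recombination was lower (-0.18, percentile 0.470, with GEN1, a resolvase, at -1.10). With a filter at 20 RPKM the p53 targets (0.18), apoptosis regulators (0.19) and homologous recombination (-0.11, percentile 16.1) lay inside the random range. Rescaled without centring, homologous recombination was at -0.07 and p53 targets at 0.28. IP changes rose with coding GC (rank correlation 0.47 across genes), on which random lists were not matched. The remaining repair lists lay within the random range (mismatch repair -0.01, nucleotide excision -0.03 with a mean of 0.09, base excision 0.04, non-homologous end joining -0.12, Fanconi anaemia -0.10, checkpoint -0.16). The other large falls were ADM, the vasodilator adrenomedullin (-2.10), the immediate-early genes FOS (-1.97, turning to 0.04 against control cells) and CYR61, a matrix-associated growth regulator (-1.73), AC245033.1, an unnamed gene model (-1.87), and MTRNR2L12, a humanin-like gene (-1.70, 2 against 6 reads, interval -5.24 to 0.59). In all 252 genes were higher and 69 lower among 8491.

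**Figure D4:**
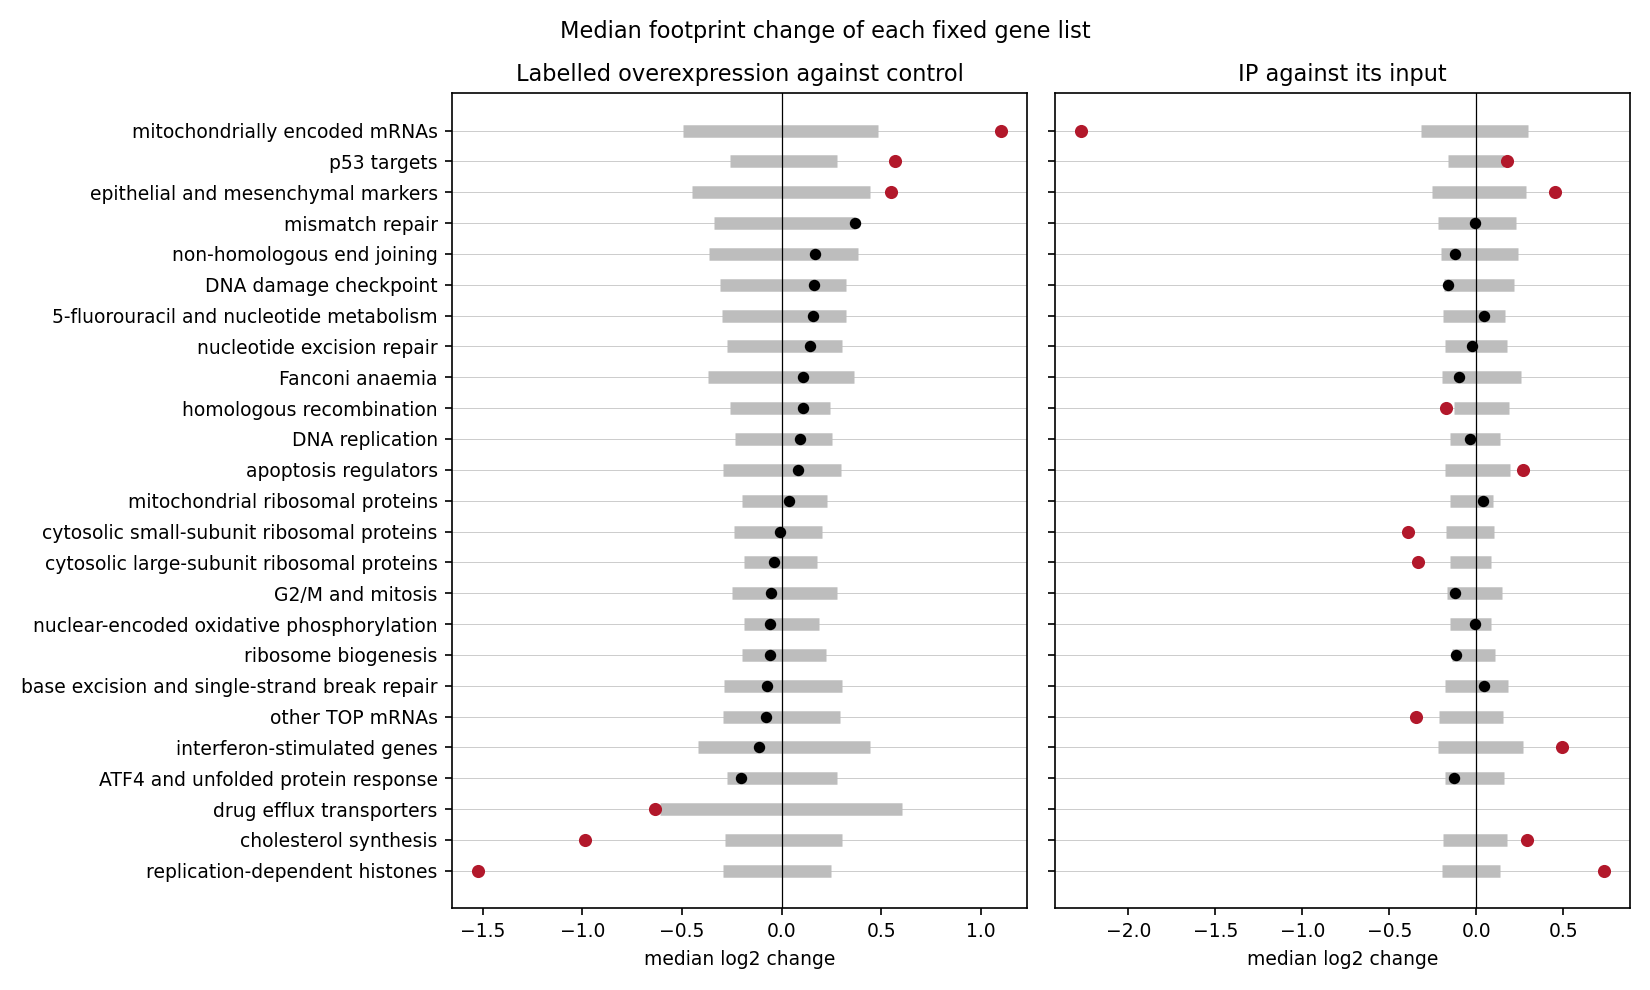
Median log2 footprint change of each gene list in the library labelled overexpression against control and in the IP against its input; grey bars hold the central 95% of random lists and red points lie outside them. Mitochondrially encoded mRNAs stood at 1.10 in the library labelled overexpression and at -2.27 in the IP.

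The comparisons were then set against each other across genes, which are not independent replicates. Footprint and RNA changes of the knockdown correlated with r = 0.78 over 7639 genes. Of the genes higher in footprints 95 were also higher in RNA (5.05 if independent), and 119 were lower in both (4.72 if independent). Footprint changes of the knockdown and of the library labelled overexpression, which share the control library and so its chance values, had r = 0.29 over 8114 genes; counting error in unchanged libraries gave 0.63. Their covariance was 0.121 against 0.0388 from counting error, and 89 genes were higher and 70 lower in both (17.2 and 18.8 if independent). Part of this overlap can come from the shared control, which cannot be split. TE changes of the knockdown and IP changes, which share no library, had r = 0.15 and a rank correlation of 0.16 over 7357 genes. Both rose with coding GC (rank correlations 0.35 and 0.47), while changes of the IP's input against control fell with it (-0.43), and at fixed GC the rank correlation of TE and IP changes over 7098 genes was 0.00, a value computed after the others were seen. Of 61 genes with higher TE 8 were higher in the IP (1.06 if independent) and 1 was lower. Of 26 with lower TE 0 were lower in the IP (0.17 if independent) and 3 were higher, too few to read.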

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

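The restrictions to 50 reads, to equal transcripts and to genes seen in RNA-seq were chosen after the data were seen. No paired analysis was possible because each group has 1 library here and no result comes from a test. Of 45 recomputed counts of changed genes, 23 stayed within 1.5 times the reported count. Of 1112 recomputed list medians, 1044 stayed within their interval, 58 moved beyond it and 10, of lists that stood apart, changed sign. Sign changes of lists that did not stand apart were not counted as such. Of 2249 recomputed changes of named genes, 1992 stayed within their range, 253 moved and 4 changed sign. The range was the counting interval, widened where needed to hold the reported change, and for TE a fixed margin around that change. Counting intervals are wide for genes with few reads, so staying within them says little there. Sign changes were counted only for genes changed 2-fold or more. Of the 44 list medians that stood apart in a comparison, 29 did so under every alternative for which random lists were drawn. None were drawn with control cells as the reference of the IP. Histones and cholesterol synthesis in the IP, counted among the 29, changed sign against that reference. With a filter at 20 RPKM histones in RNA and TE (2 members each) and drug efflux transporters in the library labelled overexpression (1 member) had too few members for a value.

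Counts are given for knockdown (KD), labelled overexpression (OE), control (CTL) and IP. There were, with a pseudocount of 5, a minimum of 1 RPKM, of 20 RPKM and no filter in turn, 430, 1194, 349 and 1390 genes changed 2-fold or more, Ribo KD vs CTL, 161, 547, 110 and 553 genes changed 2-fold or more, RNA KD vs CTL, 40, 310, 19 and 521 genes changed 2-fold or more, TE KD vs CTL, and 189, 554, 147 and 602 genes changed 2-fold or more, Ribo IP vs OE. With a pseudocount of 5 and a minimum of 20 RPKM there were 613 and 526 genes changed 2-fold or more, Ribo OE vs CTL. TE gave 173 without centring, 202 rescaled to equal totals and 52 with at least 50 reads, and the IP against control cells gave 837. Requiring at least 1 RPKM in RNA-seq gave 723 for knockdown footprints, 930 for labelled overexpression and 252 for the IP. The TE medians of homologous recombination, ribosome biogenesis and DNA replication turned to 0.0197, 0.0298 and 0.0189 without centring and to 0.0890, 0.11 and 0.10 rescaled, scalings that move all genes nearly alike and left these lists outside the random range. Epithelial and mesenchymal markers in the library labelled overexpression turned to -0.39 (at least 20 RPKM) and -0.0565 (no filter). Against control cells as the reference, the medians of histones (-0.77) and cholesterol synthesis (-0.74) turned, and so did FOS (ENSG00000170345), Ribo IP vs OE (0.0382), RPS21 (0.63), HIST2H2AC (-1.22) and HIST2H2BE (-1.20). The correlation of knockdown and labelled overexpression changes was 0.268 with at least 50 reads, and the correlation across genes of TE change on KD and IP enrichment was 0.0964 at 1 RPKM and 0.223 at 20 RPKM. A higher pseudocount or filter lowers counts by construction; otherwise the cause was not tested. Control and knockdown footprints were shallowest, with a median of 35 and 52 reads per gene.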

Other observations

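Tests of TOP mRNAs as a class, and of counting noise, reads from 1 foreign source and GC content in the IP, were chosen after the results were seen, and so were the genes named in the following 2 paragraphs. Of 7 metallothionein genes with a footprint change in the knockdown, which encode proteins that bind zinc and copper, 5 fell 2-fold or more (MT1A, MT1E, MT1G, MT1X and MT2A), while MT1M was at 0.10 and MT1F at 0.95. No list of them was fixed. The most abundant, MT2A, had footprints of 5316 RPKM in the control and 2703 RPKM in the knockdown (log2 change -1.20) and RNA of 384 RPKM and 166 RPKM (-1.28), and MT1X was at -1.29 in footprints and -1.48 in RNA, with TE changes of 0.08 and 0.19. In the library labelled overexpression MT2A was at -1.86 against control, and in the IP at 1.79 against its input. These genes are close copies, so reads can be shared among them. STC1, a secreted stanniocalcin, had 39.3 RPKM in control footprints and 640 RPKM and 988 RPKM in the library labelled overexpression and the IP.

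Footprints of genes that the RNA libraries hardly show differed between the library pairs. SPARC stood at 43.5 RPKM in the control and 51.3 RPKM in the knockdown, TFPI2, a protease inhibitor, at 33.5 RPKM and 85.4 RPKM, LYZ (lysozyme) at 23.5 RPKM and 18.3 RPKM, and ALB (albumin) at 7.22 RPKM and 7.18 RPKM, each with 0 to 2 RNA reads per library. Placental genes, without an RNA value here, were present in the same pair, CSH1 at 24.3 RPKM and 128 RPKM, CGA at 15.0 RPKM and 21.5 RPKM and CYP19A1 (aromatase) at 11.3 RPKM and 21.6 RPKM. In the other pair, S100A4 stood at 21.6 RPKM in the input and 209 RPKM in the IP, S100A14 at 16.0 RPKM and 74.3 RPKM and CRIP1 at 5.82 RPKM and 108 RPKM, with 0 or 1 RNA reads. Genes under 0.1 RPKM in both RNA libraries, histones left out, took 0.0408% of footprint reads in the control, 0.0656% in the knockdown, 0.0297% in the library labelled overexpression and 0.0976% in the IP. Genes without an RNA value, such as the placental genes above, are not in these shares. The shares cover 458 genes in control and knockdown, 657 in the library labelled overexpression and 693 in the IP. No RNA library came from the overexpressing cells.

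Ribosomal protein mRNAs lost translational efficiency in the knockdown (median -0.62 over 77 genes, interval -0.68 to -0.58; by subunit list -0.38 and -0.39 rescaled without centring). Short coding sequences do not account for it, since other genes of the same coding length had a median of 0.0289 (interval -0.01 to 0.06), nor does GC content, with a median of -0.0109 over matched genes, or abundance, with -0.0405, although the genes matched on abundance were less abundant (177 RPKM against 772 RPKM) and 105 other genes of at least 300 RPKM were at -0.07. Other TOP mRNAs, which share the 5' terminal oligopyrimidine tract but encode other proteins, had a median of -0.53 (interval -0.67 to -0.38). As a hypothesis, the change may therefore follow the TOP class rather than ribosomal proteins alone. Reads shared with pseudogenes were not tested and stay open, and there is 1 library per group.

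mRNAs from long genes fell in the knockdown, with a median of -0.77 over 200 kb. A trend with transcript length, which poorer RNA would give, is argued against by the partial rank correlation of the RNA change with transcript length at fixed span, 0.13, in the other direction. The partial correlation with coding GC, -0.20, has the size set beforehand for a GC effect, but long genes have lower GC (-0.42), so a fall with rising GC would raise long genes and is argued against as the cause. The partial correlation with span at fixed transcript length and GC was -0.35, so the trend remained with these held fixed. It comes from the same values in which the trend was seen and is no separate support. Gene span itself, for example through slower or incomplete transcription of long genes, may underlie the fall. That mechanism was not tested, and there is 1 library per group.

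Several genes of epithelial junctions, keratins and ligands were higher in the IP than in its input, a grouping read from the values and not shared by OCLN (-0.05) and TJP1 (0.26). Counting error alone is argued against by draws from unchanged proportions, which gave a mean of 3.45 and at most 10 genes changed 2-fold or more against 65 genes at least 4-fold higher. These draws hold no PCR copies and no variation between libraries, so noise from either stays open. Among 515 other genes matched on GC the median was 0.0924 (interval 0.06 to 0.12), so genes of like GC were mostly not raised to this extent. This cannot decide on GC content. Only 252 of 8491 genes were 2-fold higher in the IP, so a 2-fold median, the size set for a GC effect, was out of reach. IP changes rose with coding GC across genes (rank correlation 0.47), and a contribution of GC stays open. For a preference of RPL22L1 ribosomes, a fall of TE in the knockdown was predicted beforehand for genes 2-fold higher in the IP. Their median TE change was 0.17 over 128 genes (interval 0.08 to 0.23), above the bound set beforehand as counting against a preference. That median comes mostly from other genes, since 7 of the 65 have a TE value (median -0.16). For the 65 genes a preference therefore stays open, a reservation that was not part of the prediction. EPCAM, CDH1, KRT18, CLDN3 and CLDN4 had a median of 1.24, with KRT18 the lowest at 0.45. That median is the value of CLDN3, which had 1 read in the input and 9 in the IP. CLDN3 and CDH1 (4 and 37 reads) lay below the filter of 5 RPKM, and CLDN4 had 2 input reads. The better counted genes were EPCAM at 1.24 (140 and 418 reads) and KRT18 (2766 and 4696 reads). Reads from 1 foreign source cannot be told apart from a change of the cells: 49 genes under 1 RPKM in control RNA and at 20 RPKM or more in the IP had a median of 1.10 with quartiles from 0.45 to 2.29, neither 1 common ratio nor none, and they include histones that RNA-seq misses.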
